A study of Homo sapiens with 14 samples.

How the data were processed

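Gene expression was measured on 2-colour spotted cDNA arrays in the human lymphoblastoid lines TK6 and WTK1, 6, 12 or 24 h after exposure to nitric oxide at a dose labelled 390 micromol. Each of the 14 arrays set a treated sample against an untreated one. The groups were TK6 at 6 h (1 array), 12 h (2) and 24 h (5), and WTK1 at 6 h (1), 12 h (2) and 24 h (3), taken from the labels. Nothing in the labels says whether replicates of a group were separate cultures, so the p-value of a feature measures the spread between arrays only. The list test sets the statistics of list members against those of other genes, and Fisher's exact test counts features. Neither of these p-values treats arrays as the replicates, so a very small one is not evidence from many arrays. The title of the WTK1 array at 6 h names untreated TK6 as its reference, while its second-channel source and description name untreated WTK1.

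The deposited values of the authors are log2 ratios per probe, with 9128 probes on each array and 0 missing values. Of all values, 99.9969 percent became a whole multiple of 0.001, within 0.02 of a step, when 2 was raised to them. The share was 4.97 percent for the inverse ratio. Which channel is the numerator is not given in the sources used here. All titles name the treated sample first, and a ratio of treated over untreated is likely and was assumed throughout. The dyes, any dye swap, the background correction and the normalization are not given in the sources used here. Array medians ranged from -0.0499 to 0.0370, and the SD across probes ranged from 0.262 to 0.538. For arrays, their number limits the precision.

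Every array was centred on its median, and probes of a gene were averaged. Of the probes, 6318 carried a single gene symbol, 106 carried several and 2704 carried none. Gene identifiers of 6315 probes were found in the RefSeq gene table, 3 were not, and 0 symbols needed an update. Probes with several symbols or none were kept 1 by 1 as unnamed. This left 8634 features, of which 5824 were named genes, 462 of them with more than 1 probe.

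The 12 arrays at 12 and 24 h were fitted together in R 4.3.3 with limma 3.58.1, with a mean for each group and moderated variances (8 residual degrees of freedom, prior 4.92, prior SD 0.274). The 6 h groups hold 1 array each and were given as values with no test. The contrasts, 8 in all, were each line's ratio against 0 at 12 and at 24 h, TK6 minus WTK1 at each time, and 24 h minus 12 h in each line. All tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg within each contrast at 0.05. A ratio against 0 leaves out the spread of the untreated samples if arrays shared untreated RNA, and nothing in the labels says whether they did. It also cannot be separated from a dye bias of a gene. In the contrast of the lines such a bias cancels only between arrays of a print with the same dye orientation, which is not given in the sources used here.

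Lists of genes, 26 in all, were tested with the preset correlation of 0.01 of limma's competitive list test, and again with a correlation estimated from the residuals, where at least 5 members were measured. This held for 24 lists. Member counts were also adjusted over the list alone. The lists, groups, contrasts, named-gene rule and most alternatives were fixed before the data were examined. For each contrast, the rule named up to 10 genes with the highest and 10 with the lowest change among those past the threshold with a single symbol and the same sign on every array, or with no overlap between the groups compared. Where none passed, the 5 highest and 5 lowest moderated statistics were named and said not to pass. For each list it named up to 2 members with the highest and 2 with the lowest statistic. A set of genes was always looked up, among them CDKN1A, MDM2, GADD45A, BAX, BBC3, FAS, TNFRSF10B, PPM1D, HMOX1, PCNA and MYC. Of these, GADD45A, BAX, HMOX1 and PCNA had no probe and are not analysed here.

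Array prints differed. Print v4.0p6 held 8 arrays (the first 12 h replicate of each line, TK6 24 h replicates 1 to 3 and all WTK1 24 h arrays), v2.6p3 held 2 (TK6 24 h replicates 4 and 5) and v5.0p16 held 4 (both 6 h arrays and the second 12 h replicate of each line). Alternatives were the deposited ratios without centring, a common median absolute deviation, array quality weights, robust moderation, probes 1 by 1, only the groups compared, only print v4.0p6, print or replicate number as a block, and each replicate left out. A fit of the 24 h arrays alone, a print block for the lists and an exact permutation of list means were added after seeing the data. The smallest p of that permutation is 0.018, so it could hardly pass after adjustment over 24 lists. Its adjusted p still enters the ranges given over alternatives. No value was missing, so alternatives for missing values had nothing to change.

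The fit was tested on simulated data with known shifts. Of 100 genes shifted by 1 in TK6 at 24 h 96 percent were recovered, and 55 percent of those shifted by 0.5. In WTK1 at 24 h the shares were 87 and 10 percent. For 200 genes shifted in the contrast of the lines at 24 h they were 71 and 5 percent. Unshifted genes called numbered 5 in each line and 6 in the contrast. The simulated noise was independent between genes and arrays, had the same spread in every group, and held no print effect or dye bias. In the real data the residual SD was 0.15 in WTK1 and 0.25 in TK6 at 24 h, so these shares need not hold there. The separate background of untreated cultures, genomic positions of probes and spot intensities are not used here.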

Results

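TK6 and WTK1 are human B lymphoblastoid lines that differ in p53 allele per the labels, wild type against mutant. The comparison asks how the lines respond to nitric oxide over time. The data are log2 ratios of treated over untreated cells on 14 arrays: in TK6 1 array at 6 h, 2 at 12 h and 5 at 24 h, and in WTK1 1, 2 and 3. Each array gave a value for all 9128 probes, and their number limits the precision.

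At 24 h, TK6 cells held more RNA of p53 target genes after nitric oxide than untreated TK6 cells. CDKN1A, which encodes the cell-cycle inhibitor p21, rose 4.16-fold (log2 2.06, SE 0.15, n = 5, adjusted p = 5.7e-05 by limma) and was above 0 on all 5 arrays. TP53I3, a p53-inducible oxidoreductase, rose 2.82-fold (SE 0.22 on the log2 scale, adjusted p = 0.0026). The death receptor FAS rose by 1.26 (SE 0.17, adjusted p = 0.0012), and the BH3-only genes PMAIP1 and BBC3 rose by 1.25 (SE 0.15, adjusted p = 0.0011) and 0.85 (SE 0.13, adjusted p = 0.0036). MDM2, a ubiquitin ligase, rose by 1.29 (SE 0.25, adjusted p = 0.010), with arrays from 0.12 to 2.13. Of 32 measured p53 targets, 16 rose and 0 fell, or 21 and 0 adjusted over the list alone, with a median of 0.41 (adjusted p = 3.6e-18). TNFRSF10B at 0.34 (adjusted p = 0.099), PPM1D at 0.43 (adjusted p = 0.077) and MYC at -0.22 (adjusted p = 0.33) did not pass. The MDM2 call ended within print v4.0p6, at 0.94 (adjusted p = 0.081), and without TK6 24 h replicate 5, at 1.23 (adjusted p = 0.050), and its adjusted p ranged from 0.0045 to 0.081 over 12 alternatives. The 3 probes of PPM1D differed, at 1.58, -0.13 and -0.15.

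Cholesterol synthesis genes fell in TK6 at 24 h. Of 16 measured members 8 fell and 0 rose, or 9 and 0 adjusted over the list alone, with a median of -0.36 (adjusted p = 5.4e-07). IDI1, the isopentenyl diphosphate isomerase, fell to -1.05 (SE 0.12, n = 5, adjusted p = 0.00075 by limma). HMGCS1, the cytosolic HMG-CoA synthase, fell to -0.59 (adjusted p = 0.0028), though its 2 probes read 0.14 and -1.33. Genes of the unfolded protein and ATF4 response moved up, with 8 of 23 rising and 0 falling (9 and 0 adjusted over the list alone), a median of 0.27 and an adjusted p = 5.3e-05. Its call was lost at adjusted p = 0.073 with an estimated correlation. Its members SESN2, a stress-induced regulator of growth signalling, and WARS1, the tryptophanyl-tRNA synthetase, rose by 0.86 (adjusted p = 0.0012) and 0.66 (adjusted p = 0.0033). SESN2 is also on the list of p53 targets. The p53 and cholesterol lists held at adjusted p = 3.4e-06 and 7.3e-05 with an estimated correlation, and the apoptosis regulators at 0.020.

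Among those apoptosis regulators, 6 of 32 rose and 0 fell (6 and 1 adjusted over the list alone), with a median of 0.17 and an adjusted p = 0.0064, and 5 of its genes are also p53 targets. NF-kB targets had 7 of 26 higher and 0 lower (8 and 1 adjusted over the list alone), a median of 0.26 and an adjusted p = 0.0075, or adjusted p = 0.11 with an estimated correlation. TNFAIP3, a feedback inhibitor of NF-kB, rose by 0.84, a call that ended without TK6 24 h replicate 5 (0.80). MHC class II genes had 5 of 11 higher and 0 lower (5 and 0 adjusted over the list alone), a median of 0.23 and an adjusted p = 0.0030, or adjusted p = 0.17 with an estimated correlation. HLA-DMB, which helps to load peptides onto class II molecules, rose by 0.47, a call that ended without TK6 24 h replicates 4 or 5 (0.47 each). DNA replication and G1/S genes had 6 of 32 higher and 0 lower (9 and 0 adjusted over the list alone), a median of 0.21 and an adjusted p = 0.0075, or adjusted p = 0.55 with an estimated correlation. RRM1, the large subunit of ribonucleotide reductase, rose by 0.68. Cytosolic ribosomal protein genes had 2 of 14 lower and 0 higher (3 and 0 adjusted over the list alone), a median of -0.23 and an adjusted p = 0.013, or adjusted p = 0.52 with an estimated correlation. Within print v4.0p6 the G1/S median was 0.02 and the MHC class II median 0.26, and both calls ended. The apoptosis, NF-kB and ribosomal calls held there with the preset correlation, at medians of 0.083, 0.21 and -0.38 (adjusted p = 0.043, 0.014 and 4.4e-07 by the list test). Without TK6 24 h replicate 1 the NF-kB and ribosomal calls ended at medians of 0.25 and -0.18, the ribosomal call ended without replicate 2 at -0.24, and the G1/S call ended without replicate 4 at 0.14.

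In all, 986 of 8634 features were called in TK6 at 24 h, 500 higher and 486 lower, and 15 of them changed over 2-fold. Further genes among the highest were CTBS, a lysosomal chitobiase, at 1.48 (adjusted p = 0.0010), ENC1 at 1.40 (adjusted p = 0.00043), the lymphocyte receptor SLAMF1 at 1.27 (adjusted p = 7.5e-05), TRIM22 at 1.10 (adjusted p = 0.0051) and FGL1 at 1.01 (adjusted p = 0.0011). AKR1C1, an aldo-keto reductase, fell to -0.90 (adjusted p = 0.00043), the sulfotransferase CHST2 to -0.96 and EIF4E3 to -0.83. KCNMA1 and PLEKHM1 fell to -0.95 and -0.93 and were no longer called within print v4.0p6, at -0.46 each. Without TK6 24 h replicates 3, 4 and 5 in turn the count was 309, 320 and 162, and it was 1744 with the 24 h arrays fitted alone and 2614 with array quality weights.

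In WTK1 cells at 24 h few genes passed the test, and none of them was a p53 target. NEMF, a factor of ribosome quality control, rose by 1.85 (SE 0.24, n = 3, adjusted p = 0.013 by limma), which came from 1 of its 2 probes, at 3.32 against 0.37. KLF10, an early-response transcription factor, rose by 1.33, and the Mediator subunit MED13, the phosphatase subunit PPP2CB, the RNA-binding reader YTHDF3 and the tRNA-modifying enzyme TRIT1 rose by 0.83, 0.81, 0.75 and 0.72 (each adjusted p = 0.039). CDKN1A was at 0.34 (SE 0.20, adjusted p = 0.53), MDM2 at 0.03, FAS at 0.25, BBC3 at -0.12, TNFRSF10B at -0.03, PPM1D at -0.18 and MYC at -0.23, and these did not pass. Of the 32 p53 targets 0 were called by limma, with a median of 0.0028 (adjusted p = 0.93), and the cholesterol genes had a median of 0.03 (adjusted p = 0.93). Limma called 9 features higher and 0 lower, with 1092 at an unadjusted p under 0.05 in either direction, and 0 of 24 lists. Without WTK1 24 h replicates 1, 2 and 3 in turn 0, 0 and 1 were called, and 709 were called on a common array scale, so this count against 986 in TK6 does not measure a difference between the lines.

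The direct test of the lines at 24 h placed CDKN1A 1.72 higher in TK6 than in WTK1 (SE 0.25, n = 5 and 3, adjusted p = 0.040 by limma). It was the only named gene called. Of 8634 features 3 were called, and the others were unnamed probes 164909 (TK6 -0.61, WTK1 0.53) and 168953 (TK6 -0.58, WTK1 0.68). The p53 targets were higher in TK6 by a median of 0.41 (adjusted p = 1.8e-27, or 2.1e-09 with an estimated correlation), with 1 member called and 13 adjusted over the list alone. PMAIP1 differed by 1.16 (adjusted p = 0.23), BBC3 by 0.96 (adjusted p = 0.24), FAS by 1.02 (adjusted p = 0.50) and MDM2 by 1.26 (adjusted p = 0.80), which did not pass. Cholesterol genes were lower in TK6 by a median of -0.27 (adjusted p = 2.7e-10, or 3.8e-07 with an estimated correlation), with 0 members called by limma and 4 adjusted over the list alone. HMGCS1 was at -0.59 in TK6 and 0.30 in WTK1 (adjusted p = 0.060), and IDI1 at -1.05 and 0.02 (adjusted p = 0.10). Within print v4.0p6 the median difference was 0.43 for p53 targets and -0.28 for cholesterol genes. Print or replicate number as a block gives the same estimates for this contrast, from the same 3 arrays of each line. The CDKN1A call ended within print v4.0p6 (1.46, adjusted p = 0.11), with print as a block (1.46, adjusted p = 0.055), with replicate number as a block (1.46, adjusted p = 0.37), with the compared groups or the 24 h arrays fitted alone (each adjusted p = 0.053), without TK6 24 h replicates 1, 4 or 5 (adjusted p = 0.14, 0.12 and 0.16) and without WTK1 24 h replicates 1, 2 or 3 (adjusted p = 0.30, 0.28 and 0.33), in a range of 0.0016 to 0.37 over 17 alternatives.

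Other lists also differed between the lines at 24 h. Unfolded protein and ATF4 genes were higher in TK6 by a median of 0.26 (adjusted p = 5.0e-09, or 0.0035 with an estimated correlation, 6 members adjusted over the list alone). SESN2, which is also on the p53 list, and WARS1 differed by 0.98 (adjusted p = 0.12) and 0.76 (adjusted p = 0.22). MHC class II genes were higher by a median of 0.31 (adjusted p = 5.3e-07, or 0.011 with an estimated correlation, 0 members by limma and adjusted over the list alone). G2/M genes were lower in TK6 by a median of -0.26 (adjusted p = 5.3e-07), or adjusted p = 0.17 with an estimated correlation. Their examples are DLGAP5 at -0.72 and the mitotic kinase PLK1 at -0.45, which did not pass. Apoptosis regulators and NF-kB targets had median differences of 0.073 (adjusted p = 0.00076, or 0.0034 with an estimated correlation) and 0.089 (adjusted p = 0.0072, or adjusted p = 0.087 with an estimated correlation). Of the 32 apoptosis regulators, 5 are also on the p53 list, FAS, BBC3 and PMAIP1 among them, so the 2 lists are not separate results. Of members of these 5 lists 0 were called by limma, and 3 apoptosis regulators, 0 G2/M genes and 0 NF-kB targets were called adjusted over the list alone. Within print v4.0p6 the medians were 0.21 for unfolded protein genes, 0.20 for MHC class II, -0.34 for G2/M, 0.0065 for apoptosis regulators and 0.10 for NF-kB targets. The NF-kB call ended without TK6 24 h replicate 1 at 0.13, and the apoptosis call with replicate number as a block at 0.0065.

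More lists differed between the lines at 24 h once print was held constant. Within print v4.0p6, with the preset correlation, oxidative phosphorylation genes were lower in TK6 by a median of -0.31 (adjusted p = 1.3e-08, range 1.3e-08 to 0.65 over 17 alternatives) and proteasome genes by -0.29 (adjusted p = 0.00015, range 3.8e-05 to 0.65). Cytosolic ribosomal protein genes were lower by -0.26 (adjusted p = 0.00035, range 0.00025 to 0.90), heat shock genes by -0.34 (adjusted p = 0.0028, range 0.00032 to 0.60) and G1/S genes by -0.15 (adjusted p = 0.038, range 0.026 to 0.96). Print as a block gives the same medians for this contrast, since v2.6p3 holds only TK6 arrays, and is no separate check of them. With it the first 4 also passed, at adjusted p = 1.3e-08, 4.8e-05, 0.00025 and 0.0023, and G1/S genes did not (adjusted p = 0.098). Over all arrays the medians of the first 4 were -0.10, -0.10, -0.090 and -0.24 and did not pass (adjusted p = 0.11, 0.18, 0.30 and 0.096), nor did they at adjusted p = 0.65, 0.65, 0.70 and 0.47 with an estimated correlation, which was not run within the print. The G1/S direction turned, since over all arrays its median was 0.026 (adjusted p = 0.28, or 0.71 with an estimated correlation). The lowest adjusted p of the G1/S range belongs to the opposite direction. Without TK6 24 h replicate 1 these genes were called higher in TK6 (median 0.034, adjusted p = 0.026 by the list test). The lower heat shock level rested on 2 of 3 TK6 arrays of the print, with list means of 0.33, -0.24 and -0.21 against 0.28, 0.18 and 0.18 in WTK1. Of the members of these 5 lists 0 were called by limma over all arrays, before or after adjusting over the list alone.

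**Figure D1:**
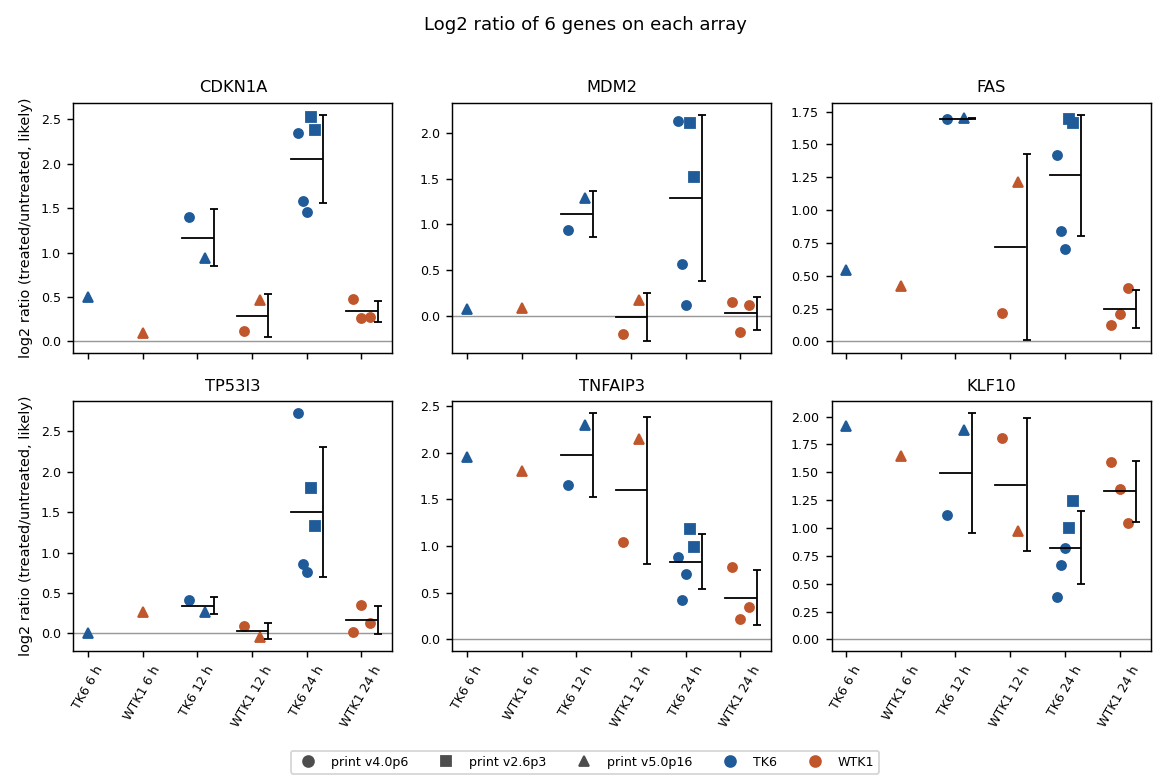
Log2 ratio of treated over untreated cells on each array (points; shape gives the array print, colour the line) for CDKN1A, MDM2, FAS, TP53I3, TNFAIP3 and KLF10, a choice made after the values were seen, by line and time (the title of the WTK1 array at 6 h names untreated TK6), with the mean and SD where a group has several arrays. CDKN1A lay between 1.46 and 2.52 on the TK6 arrays at 24 h, and its mean in WTK1 was 0.34.

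At 12 h in TK6, IL6ST, the shared receptor chain of the IL-6 family, rose 4.21-fold (log2 2.07, SE 0.26, n = 2, adjusted p = 0.0018 by limma), and TNFAIP3 rose by 1.98 (SE 0.26, adjusted p = 0.0022). SLAMF1 rose by 1.82 (SE 0.16, adjusted p = 0.00045) and the somatostatin receptor SSTR2 by 1.46 (adjusted p = 0.0010). The p53 targets FAS, PMAIP1, BBC3 and CDKN1A rose by 1.70, 1.65, 1.27 and 1.17 (adjusted p = 0.0060, 0.0046, 0.0076 and 0.029). The 2 CDKN1A probes differed, with means of 1.83 and 0.50, and read 2.6 and -0.70 on replicate 2. The largest falls among named genes were in TUBB, a beta-tubulin (-1.89, SE 0.24, adjusted p = 0.0022), the chaperone HSPA8 (-1.35, adjusted p = 0.0045), the replication factor PCLAF (-1.29) and the lamin B receptor LBR (-1.27). MDM2 at 1.11 (adjusted p = 0.15), PPM1D at 0.96 (adjusted p = 0.054), TNFRSF10B at 0.70 (adjusted p = 0.086) and MYC at 0.49 did not pass. In all 201 features were called, 160 higher and 41 lower, and 68 changed over 2-fold. The count was 71 without TK6 12 h replicate 1 and 381 without replicate 2, 1711 within print v4.0p6, 56 on a common array scale, 61 with the group fitted alone and 3 with array quality weights. Without replicate 1 CDKN1A was at 0.94 (adjusted p = 0.26) and the calls of FAS, PMAIP1, HSPA8, PCLAF and LBR also ended, and without replicate 2 the BBC3 call ended, while the adjusted p of CDKN1A ranged from 0.016 to 0.44 over 8 alternatives.

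Gene groups in TK6 at 12 h moved both ways. The p53 targets had 5 of 32 higher and 0 lower (16 and 0 adjusted over the list alone), a median of 0.48 and an adjusted p = 4.9e-08, or 0.0040 with an estimated correlation. NF-kB targets had 5 of 26 higher and 0 lower (12 and 0 adjusted over the list alone), a median of 0.48 and an adjusted p = 2.2e-06, or 0.0023 with an estimated correlation. The adhesion molecule ICAM1 and the transcription factor IRF1 rose by 1.54 (adjusted p = 0.047) and 1.30, calls that ended without TK6 12 h replicate 2 (0.71 and 0.97), and that of IRF1 also without replicate 1 (1.64). Immediate early genes had 2 of 16 higher and 0 lower (8 and 0 adjusted over the list alone), a median of 0.50 and an adjusted p = 0.00010, or 0.011 with an estimated correlation. Apoptosis regulators had 4 of 32 higher and 0 lower (8 and 0 adjusted over the list alone), a median of 0.21 and an adjusted p = 0.0010, or 0.0040 with an estimated correlation. Heat shock genes moved down, with HSPA8 and CACYBP among 2 of 14 that fell (4 adjusted over the list alone), a median of -0.44 and an adjusted p = 2.7e-05, or adjusted p = 0.075 with an estimated correlation. G2/M, G1/S, oxidative phosphorylation and cholesterol genes had medians of -0.21, -0.13, -0.21 and -0.30 (adjusted p = 0.0011, 0.026, 0.013 and 0.029), and all these calls were lost, at adjusted p = 0.43, 0.59, 0.55 and 0.12 with an estimated correlation. Of the first, second and last of these, 0 members were called by limma, and of oxidative phosphorylation genes 1 rose and 1 fell. Adjusted over the list alone, 1 G2/M gene rose and 2 fell, 0 G1/S genes changed, 1 oxidative phosphorylation gene rose and 3 fell, and 3 cholesterol genes rose and 4 fell. Without TK6 12 h replicate 1 the G2/M, G1/S and oxidative phosphorylation medians were 0.12, 0.02 and -0.02 and no longer called, the cholesterol call ended without either replicate (-0.26 and -0.27), and the immediate early call ended without replicate 2 (0.35).

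In WTK1 at 12 h, IL6ST and TNFAIP3 rose as well, by 1.73 and 1.60, along with the transcriptional repressor HES1 (1.40), KLF10 (1.39), PLS1 (1.21), CREBRF (1.15) and the histone gene H2BC12 (1.10). TUBB, LBR and the oxidoreductase ERO1A fell to -1.52, -1.17 and -0.87 (n = 2, adjusted p from 0.032 to 0.042 by limma for these and the genes above). CDKN1A was at 0.29 (adjusted p = 0.73), MDM2 at -0.01, FAS at 0.72 (adjusted p = 0.30) and BBC3 at 0.18, which did not pass. The CDKN1A probes had means of 0.07 and 0.51. Cholesterol genes were lower as a list, with a median of -0.25 (adjusted p = 0.0020, or 0.028 with an estimated correlation), 0 members called by limma and 1 that fell adjusted over the list alone. NF-kB targets had 1 member higher (1 adjusted over the list alone) and a median of 0.19 (adjusted p = 0.012, or adjusted p = 0.17 with an estimated correlation). Histone genes had 1 of 8 higher (2 adjusted over the list alone) and a median of 0.34 (adjusted p = 0.014, or adjusted p = 0.19 with an estimated correlation). The p53 targets had a median of 0.013 (adjusted p = 0.87). In all 28 features were called, 23 higher and 5 lower, against 714 without WTK1 12 h replicate 1, 104 without replicate 2, 315 within print v4.0p6, 3 on a common array scale and 0 with array quality weights or the group fitted alone, where 1033 had an unadjusted p under 0.05 in limma's fit of all groups. Without replicate 2 the calls of IL6ST (1.37), TNFAIP3 (1.04), PLS1 (1.12), CREBRF (1.22), H2BC12 (0.79), TUBB (-0.90), LBR (-0.71) and ERO1A (-0.60) ended, and without replicate 1 those of HES1 (0.94) and KLF10 (0.97). Without either replicate the calls of the cholesterol, NF-kB and histone lists ended (-0.27, 0.36 and 0.65 without replicate 1, and -0.27, 0.19 and 0.04 without replicate 2).

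Of the 23 features higher in WTK1 at 12 h, 21 were also called higher in TK6, where 0.43 would be shared by chance (Fisher's exact p = 2.7e-35, across features that are not independent). They include IL6ST, TNFAIP3, KLF10, HES1, CREBRF, H2BC12, MED13 and YTHDF3. All 5 lower features were shared, TUBB, LBR and ERO1A among them. At 24 h, 7 of the 9 features higher in WTK1 were also higher in TK6 (0.52 by chance, Fisher's exact p = 6.8e-08), among them KLF10, MED13, PPP2CB, TRIT1 and YTHDF3. Across features the mean log2 ratios of the lines correlated at r = 0.70 at 12 h and 0.56 at 24 h.

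No feature differed between the lines at 12 h by limma (0 called, 162 at an unadjusted p under 0.05), with 33 called within print v4.0p6 and 40 without WTK1 12 h replicate 2. Among named genes the highest statistics, which did not pass, were those of GEM (1.14), SLAMF1 (1.22), GBP1 (0.99, adjusted p = 0.78), SSTR2 (0.95) and GLRX (0.92), and the lowest those of ADK (-0.91), HSPA8 (-0.91), SCLY (-0.75), XRCC2 (-0.70) and LRRC58 (-0.66). CDKN1A, MDM2, BBC3 and FAS were at 0.88, 1.12, 1.08 and 0.98. The 2 CDKN1A probes had means of 1.83 and 0.50 in TK6 against 0.07 and 0.51 in WTK1. The first probe was higher in TK6 on each print. The like means of the second probe hide opposite differences. It read 1.70 in TK6 and 0.29 in WTK1 on v4.0p6, and -0.70 and 0.73 on v5.0p16. As a list, p53 targets were higher in TK6 by a median of 0.50 (adjusted p = 1.3e-17, or 5.4e-06 with an estimated correlation), with list means 0.47 apart on v4.0p6 and 0.60 apart on v5.0p16. The other lists higher in TK6 were NF-kB targets (0.22, adjusted p = 0.0013, or 0.031 with an estimated correlation), interferon-stimulated genes (0.21, adjusted p = 0.0015, or 0.00093), apoptosis regulators (0.21, adjusted p = 0.00092, or 0.0023), immediate early genes (0.23, adjusted p = 0.0011, or 0.031) and B cell identity genes (0.17, adjusted p = 0.030, or 0.031). The list means of immediate early genes were 0.03 apart on v4.0p6 and 0.51 apart on v5.0p16. In the same order of prints, the differences were 0.24 and 0.29 for NF-kB and 0.15 and 0.23 for interferon genes. They were 0.32 and 0.19 for apoptosis and 0.24 and 0.15 for B cell genes. Of the apoptosis regulators, 5 are also p53 targets. G1/S, G2/M, heat shock and oxidative phosphorylation genes were lower in TK6, at -0.18, -0.14, -0.26 and -0.14 (adjusted p = 0.00092, 0.022, 0.00043 and 0.0039), and these calls were lost, at adjusted p = 0.54, 0.65, 0.11 and 0.59 with an estimated correlation. Their list means differed by -0.37, -0.27, -0.42 and -0.26 on v4.0p6 and by 0.07, 0.06, -0.10 and -0.04 on v5.0p16. Of all members of these lists 0 were called by limma, and 1 interferon and 1 immediate early gene were called adjusted over the list alone. The p53 call held without any 1 array. Without WTK1 12 h replicate 1 the calls of NF-kB (0.15), interferon (0.16), apoptosis (0.21), immediate early (0.30), B cell (0.054), G1/S (-0.16), heat shock (-0.37) and oxidative phosphorylation genes (-0.26) ended, and without replicate 2 those of interferon (0.11), immediate early (0.18), B cell (0.30), G2/M (0.0083), heat shock (-0.27) and oxidative phosphorylation genes (-0.087). Without TK6 12 h replicate 1 the calls of interferon (0.21), apoptosis (0.28), B cell (0.18), G1/S (-0.039), G2/M (0.20), heat shock (-0.15) and oxidative phosphorylation genes (-0.027) ended, and without replicate 2 those of NF-kB (0.12), interferon (0.19), immediate early (0.11) and B cell genes (0.067).

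**Figure D2:**
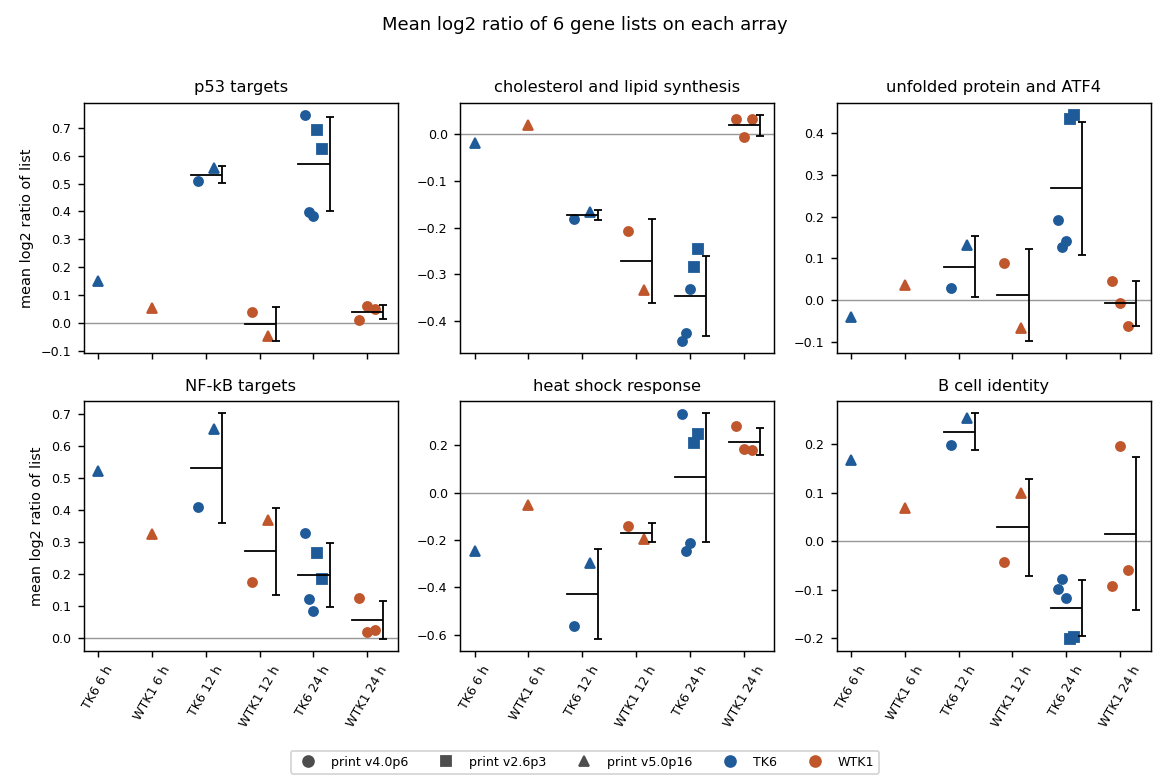
Mean log2 ratio of treated over untreated cells over the measured members of 6 gene lists, chosen after the values were seen, on each array (points; shape gives the array print, colour the line), by line and time (the title of the WTK1 array at 6 h names untreated TK6). The p53 target mean was 0.57 over the TK6 arrays and 0.04 over the WTK1 arrays at 24 h.

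Between 12 and 24 h, TK6 ratios of GBP1, an interferon-induced GTPase, fell by 1.20 (adjusted p = 0.024 by limma), from 0.79 to -0.41. DPH3, which takes part in diphthamide synthesis, went from 0.95 to -0.34 (adjusted p = 0.024) and SSTR2 from 1.46 to 0.35 (adjusted p = 0.049). Unnamed probes 159765 and 168875 rose by 1.23 and 1.79. These 5 were all the features called (2 higher, 3 lower, 1095 at an unadjusted p under 0.05), and CDKN1A was 0.89 higher at 24 h (adjusted p = 0.27). The 2 CDKN1A probes went from means of 1.83 and 0.50 at 12 h to 2.00 and 2.11 at 24 h. B cell identity genes moved down by a median of -0.50 (adjusted p = 0.0041, or 0.0070 with an estimated correlation). G1/S, heat shock, unfolded protein, MYC target and MHC class II genes were higher at 24 h by medians of 0.35, 0.37, 0.18, 0.17 and 0.39 (adjusted p = 4.7e-06, 3.9e-06, 0.0094, 0.0066 and 0.0041), while NF-kB and immediate early genes were lower by -0.28 and -0.30 (adjusted p = 0.013 and 0.0041). These 7 calls were lost, at adjusted p = 0.31, 0.083, 0.31, 0.38, 0.27, 0.20 and 0.11 with an estimated correlation. No member of these lists was called by limma. Adjusted over the list alone, 1 G1/S, 3 heat shock and 2 unfolded protein genes rose, and 1 unfolded protein, 2 NF-kB, 4 immediate early and 2 B cell genes fell. With print as a block the calls of the B cell (-0.22), unfolded protein (0.11), MYC (0.17), MHC class II (0.31), NF-kB (-0.23) and immediate early lists (-0.31) ended, those of G1/S (0.24) and heat shock genes (0.40) held, and G2/M genes passed as well (0.26, adjusted p = 0.0043, in a range of 0.00096 to 0.99 over 13 alternatives). Without TK6 12 h replicate 2 the B cell (-0.36), MHC class II (0.28), NF-kB (-0.17), immediate early (-0.18) and unfolded protein (0.25) calls ended, and without replicate 1 the MYC (0.10) and unfolded protein (0.12) calls. The calls of DPH3, GBP1 and SSTR2 held in 6, 5 and 2 of 15 alternatives. The count of 5 was 85 with print as a block, 139 within print v4.0p6, 0 on a common array scale, with quality weights, with the groups fitted alone or without TK6 12 h replicate 1, 46 without replicate 2, and 1 or 2 without any TK6 24 h array.

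In WTK1, cholesterol genes were higher at 24 h than at 12 h by a median of 0.25 (adjusted p = 0.0011, or 0.039 with an estimated correlation), with IDI1 at 0.90 and HMGCS1 at 0.67. Heat shock and G2/M genes were higher by medians of 0.46 and 0.28 (each adjusted p = 0.00011), and histone and NF-kB genes were lower by -0.42 and -0.19 (adjusted p = 0.0035 and 0.032). These 4 calls were lost, at adjusted p = 0.18, 0.50, 0.15 and 0.26 with an estimated correlation. Adjusted over the list alone, 2 cholesterol and 3 heat shock genes rose, 2 histone genes fell, and 0 G2/M and 0 NF-kB genes changed. Limma called 0 features (420 at an unadjusted p under 0.05). Among named genes the highest statistics, not passing, were those of TUBB (1.48), GLRX, ENDOD1, LBR and PRKDC, and the lowest those of PLS1 (-1.73), CREBRF (-1.54), HAUS3, H2BC12 and MPHOSPH8. With print as a block 44 features were called, the cholesterol, heat shock and G2/M medians were 0.33, 0.65 and 0.41, the histone (-0.09) and NF-kB (-0.03) calls ended, and oxidative phosphorylation (0.30, adjusted p = 0.013, range 0.013 to 0.97) and proteasome genes (0.25, adjusted p = 0.038, range 0.038 to 0.85) passed as well. Without WTK1 12 h replicate 1 the cholesterol, heat shock and G2/M calls ended (0.29, 0.31 and 0.04) and 103 features were called, and without replicate 2 the cholesterol call ended (0.30). The histone and NF-kB calls ended without WTK1 12 h replicates 1 (-0.71 and -0.36) or 2 (-0.24 and 0.015), and the NF-kB call without WTK1 24 h replicate 2 (-0.16).

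At 6 h each line has 1 array, and no test was run. The WTK1 array is the one whose title names untreated TK6 while its source and description name untreated WTK1. TNFAIP3 was at 1.96 in TK6 and 1.80 in WTK1, KLF10 at 1.91 and 1.65, IL6ST at 1.77 and 1.33, HES1 at 2.06 and 1.13, ICAM1 at 2.00 and 1.15, and the histone gene H2AC6 at 2.07 and 2.30. SSTR2 was at 1.76 and 0.73 and SLAMF1 at 1.33 and 0.61. CDKN1A was at 0.50 and 0.10, where its probes read 1.52 and -0.53 in TK6 and 0.92 and -0.73 in WTK1. MDM2 was at 0.08 and 0.09, FAS at 0.54 and 0.42, BBC3 at 0.88 and 0.60, PPM1D at 0.93 and 0.10, TNFRSF10B at 0.50 and 0.12, and MYC at 0.71 and 0.72. The p53 targets had means of 0.15 and 0.05, and NF-kB targets 0.52 and 0.33.

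Arrays of a print resembled each other. The median correlation across features, which are not independent replicates, was 0.34 between arrays of a shared print and line, 0.29 between arrays of a shared print and different lines, and 0.19 between arrays of different prints of a line. The largest was 0.76, between TK6 24 h replicates 4 and 5. The lowest was -0.20, between the 2 replicates of WTK1 at 12 h, which are of different prints. The 2 replicates of TK6 at 12 h, also of different prints, correlated at 0.12, so the 12 h means rest on arrays that are unlike. No pair of arrays was identical.

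**Figure D3:**
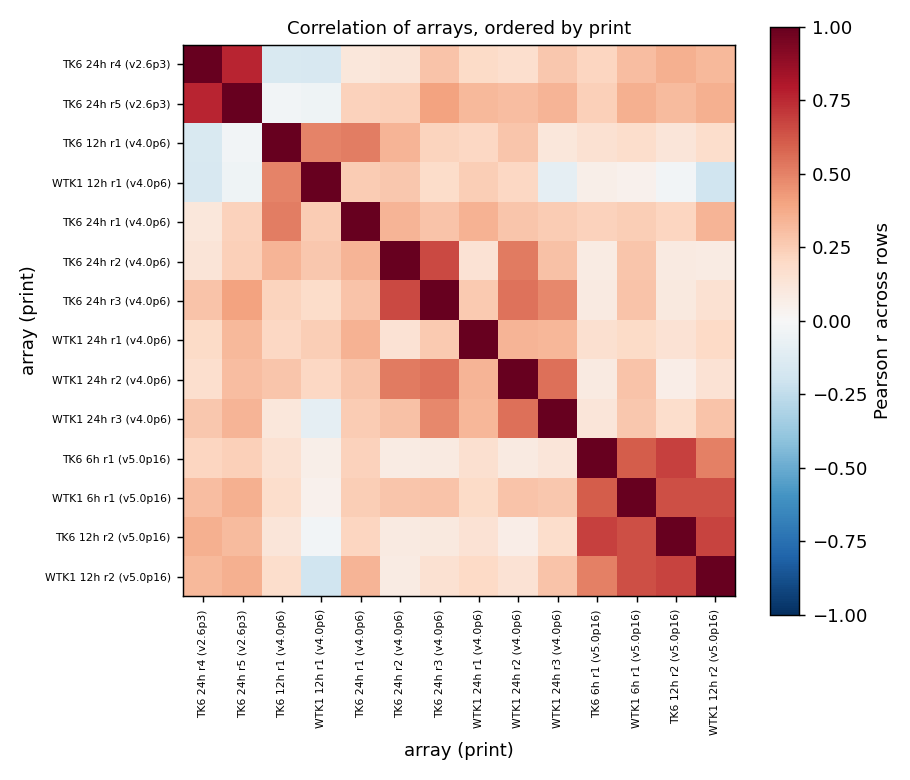
Pearson correlation across features of the log2 ratios between all 14 arrays, with arrays ordered by print (the title of the WTK1 array at 6 h names untreated TK6). Correlations lay between -0.20 and 0.76, with a median of 0.34 between arrays of a shared print and line and 0.19 between arrays of different prints of a line.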

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

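The split test of the lines at 24 h and the test of a spot or dye bias at 12 h were written beforehand; the tests of array number, of scale, of pooled spread, of print, of compressed ratios and of a shared batch were chosen after the results were seen.

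More features were called in TK6 than in WTK1 at 24 h, 986 against 9. The number of arrays does not account for all of it, since 10 subsets of 3 TK6 arrays gave a median of 61 calls, in a range of 22 to 678. The scale of the arrays or a spread pooled with other groups may account for the rest, since the counts were 1001 and 709 on a common scale, a ratio of 1.41, and 779 and 600 with each group fitted alone, a ratio of 1.30. Pooling with the 12 h arrays alone may account for a part but not for all of it. The 24 h arrays fitted alone gave 1744 and 145, against 986 and 9, and a ratio of 12.0 remained. In the direct test 3 features differed, and 1 of 56 splits of the 8 arrays, the real one, gave as many (highest other 1), so chance can be excluded only over splits that ignore print, and with print as a block 1 was called. A wider response in TK6 stays open and is not shown by the counts.

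Targets of p53 were higher in TK6 than in WTK1 at 24 h, by a median of 0.41. Array print does not account for it, since the median was 0.43 within the print both lines share (adjusted p = 5.4e-21, in a range of 4.7e-30 to 0.14 over 17 alternatives). Ratios compressed as a whole on the WTK1 arrays do not either: the 16 called targets kept a median of 0.093 of their TK6 ratio in WTK1, against 0.70 for the 484 other features called higher, and 0 percent of 10000 random sets were as low. An exact permutation of the list means per array (0.57 and 0.04, difference 0.53) gave p = 0.018, the smallest that 56 splits allow, and 0.14 adjusted over the lists. With so few splits the adjusted value could hardly pass, so it decides nothing. These splits also mix prints. Within v4.0p6 the difference was 0.47, and the permutation gave p = 0.1, the smallest that 20 splits allow. A biological difference between the lines stays open as a hypothesis and was not tested. The labels give the lines different p53 alleles, but each allele is held by a single line. The allele therefore cannot be told apart from any other difference between the lines.

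The lines shared 26 called features at 12 h, 21 higher and 5 lower. A bias of spots or dyes on a print would persist on the 24 h arrays of print v4.0p6, where the signed median was 0.47 of that at 12 h in TK6 (interval 0.35 to 0.61) and 0.54 in WTK1 (0.36 to 0.68). Both lie under the bound set beforehand, but the interval, which was added after the ratios were seen, crosses it in WTK1, so a bias cannot be told apart from a shared response. The interval holds 95 percent of 10000 resamples of the 26 features with the arrays held fixed. It therefore leaves out the spread between arrays and takes features as independent. These features were chosen by their calls at 12 h, which by itself can lower the ratio. A batch common to both lines cannot be told apart for these 26 features either, since the labels give only the print. A shared response to nitric oxide stays open and was not tested.

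Arrays that stood apart from their group were few: of 87 groups of values tested, 3 had such an array, and chance flags about 1 in 20 groups. In TK6 at 24 h, XRCC4 was at -1.01 in replicate 3 against -0.62 to -0.54 in the others. GZMA was at -1.04 in replicate 1 against -0.58 to -0.46. The mean of the immediate early genes was 0.15 in replicate 4 against 0.05 to 0.08.

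The remaining results passed the test of the difference between lines or times over all arrays, with the preset correlation for lists, and many of these calls ended in an alternative. TK6 minus WTK1 at 24 h gave CDKN1A 1.72, unnamed probe 164909 -1.14 and unnamed probe 168953 -1.26. The list medians of that contrast were 0.41 for p53 targets, -0.26 for G2/M, 0.26 for unfolded protein, 0.089 for NF-kB, 0.073 for apoptosis, -0.27 for cholesterol and 0.31 for MHC class II genes. With an estimated correlation 5 of these 7 calls were kept and those of G2/M and NF-kB were lost, and the apoptosis median was 0.0065 within print v4.0p6. The same contrast at 12 h gave medians of 0.50 for p53 targets, -0.14 for G2/M, -0.18 for G1/S, -0.26 for heat shock, 0.22 for NF-kB, 0.21 for interferon, 0.21 for apoptosis, -0.14 for oxidative phosphorylation, 0.23 for immediate early and 0.17 for B cell genes. With an estimated correlation 6 of these 10 were kept and those of G2/M, G1/S, heat shock and oxidative phosphorylation genes were lost. The list means of G2/M and G1/S genes differed by -0.27 and -0.37 on v4.0p6 and by 0.06 and 0.07 on v5.0p16. Those of immediate early genes differed by 0.03 on v4.0p6 and by 0.51 on v5.0p16. From 12 to 24 h in TK6, DPH3 differed by -1.29, GBP1 by -1.20, SSTR2 by -1.11, unnamed probe 159765 by 1.23 and unnamed probe 168875 by 1.79. List medians over that time in TK6 were 0.35 for G1/S, 0.37 for heat shock, 0.18 for unfolded protein, -0.28 for NF-kB, -0.30 for immediate early, 0.17 for MYC target, -0.50 for B cell and 0.39 for MHC class II genes. With an estimated correlation only 1 of these 8 calls, that of B cell genes, was kept, and it ended with print as a block (-0.22). Over the same time in WTK1 they were 0.28 for G2/M, -0.42 for histone, 0.46 for heat shock, -0.19 for NF-kB and 0.25 for cholesterol genes. With an estimated correlation only 1 of these 5, that of cholesterol genes, was kept, and with print as a block the histone (-0.09) and NF-kB (-0.03) calls ended.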

How the results depend on the processing

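The fit of the 24 h arrays alone, the print block for lists and the permutation of list means were chosen after seeing the data. Counts are given for TK6 at 24 h, WTK1 at 24 h, TK6 at 12 h, WTK1 at 12 h, the lines at 24 h, the lines at 12 h, TK6 over time and WTK1 over time, against 986, 9, 201, 28, 3, 0, 5 and 0. Deposited ratios (953, 9, 156, 25, 3, 0, 4, 0), robust moderation (989, 9, 196, 27, 3, 0, 4, 0) and probes 1 by 1 (1041, 10, 197, 28, 4, 0, 6, 0) kept every count within 1.5 times. On a common scale they were 1001, 709, 56, 3, 11, 0, 0 and 0. With array quality weights they were 2614, 1883, 3, 0, 63, 0, 0 and 0. With only the groups compared they were 779, 600, 61, 0, 5, 0, 0 and 0. Within print v4.0p6 they were 1105, 476, 1711, 315, 2, 33, 139 and 224, where each 12 h group held 1 array that was assumed to vary like the others. With print as a block the last 4 contrasts gave 1, 0, 85 and 44, and with replicate number as a block 0, 0, 0 and 0. The 24 h arrays alone gave 1744, 145 and 5 for TK6, WTK1 and their difference, with all 986 and 9 features among them. On a common scale 918 of the 986 and all 9 were kept, and with weights 967 and 9. Leaving out 1 replicate gave 162 to 942, 0 to 1, 71 to 381, 104 to 714, 0 to 2, 0 to 40, 0 to 46 and 0 to 103. A group left with 1 array was assumed to vary like the others. The split of WTK1 at 24 h became 569 higher and 140 lower on a common scale, and that of the lines 7 and 4. Arrays of the lines with the same replicate number had centred r of 0.166, 0.335 and 0.0886 at 24 h, and 0.453 at 12 h, where the number also gives the print. Unlike numbers at 12 h had -0.453. With 2 centred arrays in a group that value must be the opposite of the other, so it adds no comparison.

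The p53 list shift kept its direction and call in TK6 at both times and between the lines at 12 h in every alternative run. Between the lines at 24 h it did so in all but the exact permutation of list means (0.53, adjusted p = 0.14, where 56 splits set the smallest p). The other 6 list calls of that contrast ended there too, but a permutation of so few splits could hardly pass for any list. The direction of the list test reversed for G1/S genes between the lines at 24 h within print v4.0p6 (-0.15, adjusted p = 0.038, range 0.026 to 0.96) and for G2/M genes between the lines at 12 h without TK6 12 h replicate 1 (0.20) and without WTK1 12 h replicate 2 (0.0083), in a range of -0.42 to 0.20. The 0.026 of the G1/S range was a call of higher in TK6, without TK6 24 h replicate 1 (median 0.034). Medians crossed 0 while calls ended for G2/M (0.12) and G1/S genes (0.021) in TK6 at 12 h without replicate 1, for NF-kB genes in WTK1 over time without 12 h replicate 2 (0.015), and for MYC targets in TK6 over time with replicate number as a block (-0.041). With an estimated correlation 163 list results stayed on their side of the threshold and 29 no longer passed. With replicates left out 778 list results and 480 gene results kept their side, 56 and 185 no longer passed, and 28 and 3 passed newly. Calls gained with print as a block, 8 in all, were those of 4 lists between the lines at 24 h, proteasome genes between them at 12 h (-0.087), and 3 lists over time. With replicate number as a block 7 list calls were gained and 5 ended. Those gained were the same 4 lists between the lines at 24 h, ribosomal (-0.27) and cholesterol genes (-0.24) in TK6 over time, and MYC targets in WTK1 over time (0.28). For the lines at 24 h both blocks rest on the estimate within print v4.0p6, so these 4 gains are not separate checks. Those that ended were apoptosis regulators between the lines at 24 h (0.0065), B cell genes between them at 12 h (0.17), and unfolded protein (0.12), MHC class II (0.28) and MYC lists in TK6 over time. The calls of CDKN1A between the lines at 24 h and of DPH3, GBP1 and SSTR2 in TK6 over time also ended. Genes gained calls in some alternatives: MYC in TK6 at 24 h within print v4.0p6 (-0.34), PPM1D there with weights (0.41), with the 24 h arrays alone (0.43) and without replicate 1 (0.55), and BBC3 between the lines at 24 h with weights (0.77). At 12 h PPM1D in TK6 (1.46) and FAS in WTK1 (1.22) gained calls without replicate 1 of their line. The causes were not tested beyond the fewer arrays in a fit. Spot intensities are not given, so signal over background sets a limit that is unknown here.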

Other observations

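The alternatives and overlaps in this part add no test beyond the list and gene tests fixed beforehand, and the genes singled out by name follow the rule for lists.

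Immune and DNA repair genes in TK6 at 24 h went both ways within their groups. Among 27 interferon-stimulated genes 6 rose and 3 fell (7 and 3 adjusted over the list alone), with a median of 0.08 (adjusted p = 0.16 by limma). TAP1, a peptide transporter for antigen presentation, rose by 0.82, while IFIT1 and GBP1 fell to -0.50 and -0.41. The IFIT1 call ended without TK6 24 h replicate 5 (-0.48) and the GBP1 call without replicates 3, 4 or 5 (-0.35, -0.41 and -0.43). Of 4 MHC class I genes 2 rose, with a list mean of 0.30 over the arrays, too few for a test. Among 40 DNA repair genes 5 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.06 (adjusted p = 0.16). RAD51C, a recombination factor, and DDB2, a p53-inducible damage sensor, rose by 0.92 and 0.78, while XRCC4, of end joining, and MSH6, of mismatch repair, fell to -0.68 and -0.62. The MSH6 call ended without TK6 24 h replicate 3 (-0.49).

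Apart from the cholesterol and unfolded protein genes given above, metabolic and stress groups of TK6 at 24 h did not pass as lists over all arrays. By limma 2 of 6 iron-handling genes rose, 2 of 18 glycolysis and hypoxia genes rose and 1 fell, 1 of 29 oxidative phosphorylation genes rose and 4 fell, 1 of 14 heat shock genes rose, 1 of 13 NRF2 targets fell, and 0 of 16 proteasome genes were called. ISCU, the scaffold of iron-sulfur cluster assembly, rose by 0.96, while the 6 iron-handling genes had a median of -0.04, a mean of 0.13 and a test pointing up (adjusted p = 0.23). NRF2 targets had a median of 0.08 with a test pointing down (adjusted p = 0.62), and SLC7A11, a cystine transporter, was at 1.45 (SE 0.97, adjusted p = 0.35) with arrays from 0.42 to 4.35. Heat shock, glycolysis and hypoxia, oxidative phosphorylation and proteasome genes had medians of 0.05, -0.04, -0.03 and 0.05. Oxidative phosphorylation genes had list means of -0.28 to -0.16 on the TK6 arrays of print v4.0p6 and of 0.19 and 0.22 on those of v2.6p3, and within v4.0p6 they fell as a list, with a median of -0.18 (adjusted p = 0.00029, in a range of 0.00029 to 0.90 over 11 alternatives). MT1X, the only metallothionein measured, was at 0.42. MYC targets had a median of 0.15 (adjusted p = 0.051, and past the threshold in 4 of 11 alternatives). G2/M genes had a median of -0.10 (adjusted p = 0.16), and within v4.0p6 one of -0.18 that passed (adjusted p = 0.00053, in a range of 0.00053 to 0.78 over 11 alternatives). The other medians were histones 0.16 (adjusted p = 0.62), immediate early genes -0.02 with a mean of 0.09 and a test pointing up (adjusted p = 0.39), and B cell identity genes -0.11 (adjusted p = 0.23).

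Markers of other cell types did not move as groups in TK6 at 24 h. T and NK cell genes had a median of -0.06 (adjusted p = 0.68), with NKG7 up by 0.84 and GZMA down to -0.62, myeloid genes -0.07 with a test pointing up (adjusted p = 0.89), and epithelial, fibroblast and erythroid genes 0.04 (adjusted p = 0.70). In WTK1 at 24 h the lists nearest to the threshold were G2/M and heat shock genes, with medians of 0.11 and 0.30 (each adjusted p = 0.082).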
